A study of Homo sapiens with 12 samples.

How the data were processed

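RNA from 12 cultures was hybridised to Affymetrix arrays, 1 array per culture, as biotin-labelled cRNA per the labels' protocols. Groups were taken from the labels: parental (2 arrays), weakly metastatic SCP variants (3), highly metastatic post-dormancy sublines (6) and the mildly metastatic subline PD2R (1). The labels number replicates only for the parental line. The data were analysed with GeneSpring per the series design text; the signal algorithm, its version and the scaling target are not given in the sources used here.

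The deposited values are linear ratios for 22283 probe sets. What the ratio refers to was inferred from the values: within each of 19568 probe sets the median over the 12 arrays was 1, and in the remaining 2715 it was lower. In those 2715 probe sets the values of an array were whole multiples of a single step, within 0.01 of a step plus an allowance for rounding in proportion to the value. The ratios therefore behave as each array's scaled signal divided by the probe set's median, or by a fixed floor where the median is lower. Taking that step as 0.1 signal units makes the floor 10, so the absolute scale is inferred, and differences between arrays do not depend on it. For every other probe set the divisor was found as the smallest one that turns all 12 ratios into whole steps. This gave a divisor for 100% of the 19568 probe sets, the lowest being 10.0, and array medians between 126.2 and 126.3, a range of 0.083%. The recovered values lay a median of 3.5e-05 steps from a whole step, and at most 0.0595. The search was tested on 500 simulated probe sets and recovered 100% of them.

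The analysis had been planned for log or linear values, and the deposited ratio was neither; the recovered signals were treated as linear values. Array medians already matched within 5%, so no scaling was applied. Signals were floored at the 20th percentile over all arrays (16.7 units, 4.06 on the log2 scale) and log2 transformed. Of the values used, 15.3% lay at this floor. Where a whole group lay at the floor, a fold is given as a lower bound. Fold changes of dim genes are understated by the floor.

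Probe sets were named from the platform's own annotation, in which 19065 have 1 gene symbol, 1043 have several and 2107 have none, besides 68 control probe sets. Of these, 19053 matched an NCBI gene identifier in the RefSeq table for GRCh38.p14, and no symbol needed updating. Probe sets with several symbols or none were left out of gene counts, and list members without a named probe set were not analysed here. Each gene was represented by its probe set with the highest mean, which gave 11963 genes. No filter on dim genes was applied.

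Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with all 12 arrays in 1 fit so that the groups share 1 estimate of the spread, and Benjamini-Hochberg adjustment at 0.05. SCP6 and PD2R, when compared alone, were terms of their own. Gene lists were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 24 lists. The position of a line is the median, over genes called without it, of its distance from the weak SCP mean divided by the distance between the group means. The 5 comparisons, the gene lists, the tests, most of the alternatives and the rule for naming genes were fixed before the data were examined. That rule takes VCAM1 in every comparison. It also takes the 12 largest increases and decreases (6 and 6 outside the first comparison) among genes with an adjusted p under 0.05 whose groups do not overlap, and up to 4 members of each list with the smallest p.

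The fits were tested on simulated values for 11963 genes with 100 genes changed at each size, all with a mean log2 signal above 7. Recovery in dimmer genes was not tested. The simulated noise was independent between arrays and genes, so related lines and array sets were not represented. False calls were 9 of 179 for high PD against weak SCP. They were 14 of 166 for high PD against the parental line and 7 of 141 for weak SCP against the parental line. In the comparison of high PD and weak SCP, 73% of log2 changes of 1 and 97% of changes of 2 were recovered. The shares were 27% and 78% for high PD against SCP6, 57% and 95% for high PD against the parental line, 41% and 93% for weak SCP against the parental line, and 32% and 84% for PD2R. Alternatives covered normalization, centring, dim-gene filters, the summary of probe sets, the variance model, a 2-fold minimum, the arrays in the fit, the floor and leaving out each array. The deposited ratios without a floor, cyclic loess normalization and differences relative to genes of like brightness were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.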

Results

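Messenger RNA was measured on 12 Affymetrix arrays, each hybridised with RNA from sub-confluent cultures of the human breast cancer cell line MDA-MB-231 or of a line derived from it. The parental line was measured on 2 arrays. The derivatives formed the other groups: 3 single-cell variants described as weakly metastatic (SCP3, SCP4 and SCP6), 6 post-dormancy sublines described as highly metastatic (PD1 and PD2A to PD2E), and 1 post-dormancy subline described as mildly metastatic (PD2R). PD1 was derived from SCP6, and the PD2 sublines were derived from PD1. In what follows, high PD stands for the 6 highly metastatic sublines and weak SCP for the 3 weakly metastatic variants. One value was formed for each of 11963 genes. Each derivative was represented by 1 array, so that p-values rest on the spread between related lines, pooled over the groups. The number of arrays limits the precision.

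The first comparison asked how the highly metastatic post-dormancy sublines differed from the weakly metastatic variants. VCAM1, a cell surface receptor for integrins and the gene named in the study's title, was higher in high PD than in weak SCP by 3.66 ± 0.60 on the log2 scale (SE, n = 6 and 3, limma adjusted p = 0.00255). This was a 12.7-fold difference. Its log2 signal was 10.25 ± 0.59 (SD, n = 6) in high PD and 6.58 ± 1.53 (SD, n = 3) in weak SCP, and all 6 high PD arrays lay above the highest weak SCP array. The SCP lines differed widely among themselves, at 5.25 in SCP3, 8.25 in SCP4 and 6.25 in SCP6. The SE and the limma adjusted p rest on a spread pooled over the groups, which does not fully reflect the wider spread of weak SCP. An exact two-sided permutation test of the group means over the 84 splits gave p = 0.0238, the smallest value these splits can give.

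Secreted inflammatory factors made up most of the largest increases. CSF3, the granulocyte colony-stimulating factor, was higher in high PD by a log2 difference of 7.87 (limma adjusted p = 4.43e-08). Weak SCP lay at the floor of the measurement on 1 of 3 arrays and near it on the others, so that this size depends on where the floor is set. C3, the central complement component, was at the floor on all 3 weak SCP arrays, so that its difference of 5.67 on the log2 scale is a lower bound, at least 51.0-fold. The neutrophil-attracting chemokine CXCL1 was higher by 5.36 ± 0.54, and IL32, at the floor on 1 weak SCP array, by 4.36 ± 0.59. Their weak SCP SDs were 1.14 and 1.62 (n = 3), which the pooled SE does not fully reflect. The interleukin-1 genes IL1A and IL1B were higher by 4.05 and 4.01, and IL6 by 3.87. A second, dim probe set of IL1A differed by -0.35 and did not pass, whereas that of IL1B differed by 3.83. Some of these genes were also high in the parental line. The mean log2 signal of C3 was 8.77 in the parental line and 9.73 in high PD. It was 9.02 and 10.34 for CXCL1, and 8.86 and 9.67 for IL32. Much of these 3 differences therefore lay between weak SCP and the parental line. For CSF3 the means were 5.84 and 12.03, and for IL1A 5.60 and 10.26. RRAD, a small GTPase, was higher by 4.01, GPRC5B, at the floor on 1 weak SCP array, by 3.72, with another probe set at 0.99, and FKBP8 by 3.76, with other probe sets at 0.80 and -0.16. MELTF, a membrane-bound transferrin relative, was at least 12.2-fold higher, being at the floor on all weak SCP arrays.

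The largest decreases included genes of several kinds. MATN2, an extracellular matrix protein, was lower in high PD by a log2 difference of -4.89 ± 0.67 (SE, adjusted p = 0.00105), with 5 of the 6 high PD arrays at the floor. CDH11, a mesenchymal cadherin, differed by -4.52 ± 0.74, and both of its probe sets passed. As for VCAM1, the SE and adjusted p rest on a pooled spread. The weak SCP SD was 1.96 for MATN2 and 1.71 for CDH11 (n = 3), which the SE does not fully reflect. The floor also narrows the spread of high PD. The peptide-processing enzyme CPE differed by -3.86, the transcriptional inhibitor ID3 by -3.79, the non-muscle myosin MYH10 by -3.58 and the guanine nucleotide exchange factor DOCK2 by -3.53. The ligand WNT5B was at the floor on all 6 high PD arrays and at least 11.5-fold lower. LBH, C4BPB, IRX5, ENPP4 and COCH differed by -3.24, -3.21, -3.12, -2.99 and -2.95. High PD was at the floor on 5 of 6 arrays for CPE, LBH and COCH, on 4 for CDH11 and DOCK2, on 3 for IRX5 and ENPP4 and on 1 for C4BPB, so that these sizes are understated and give no order among the genes.

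**Figure D1:**
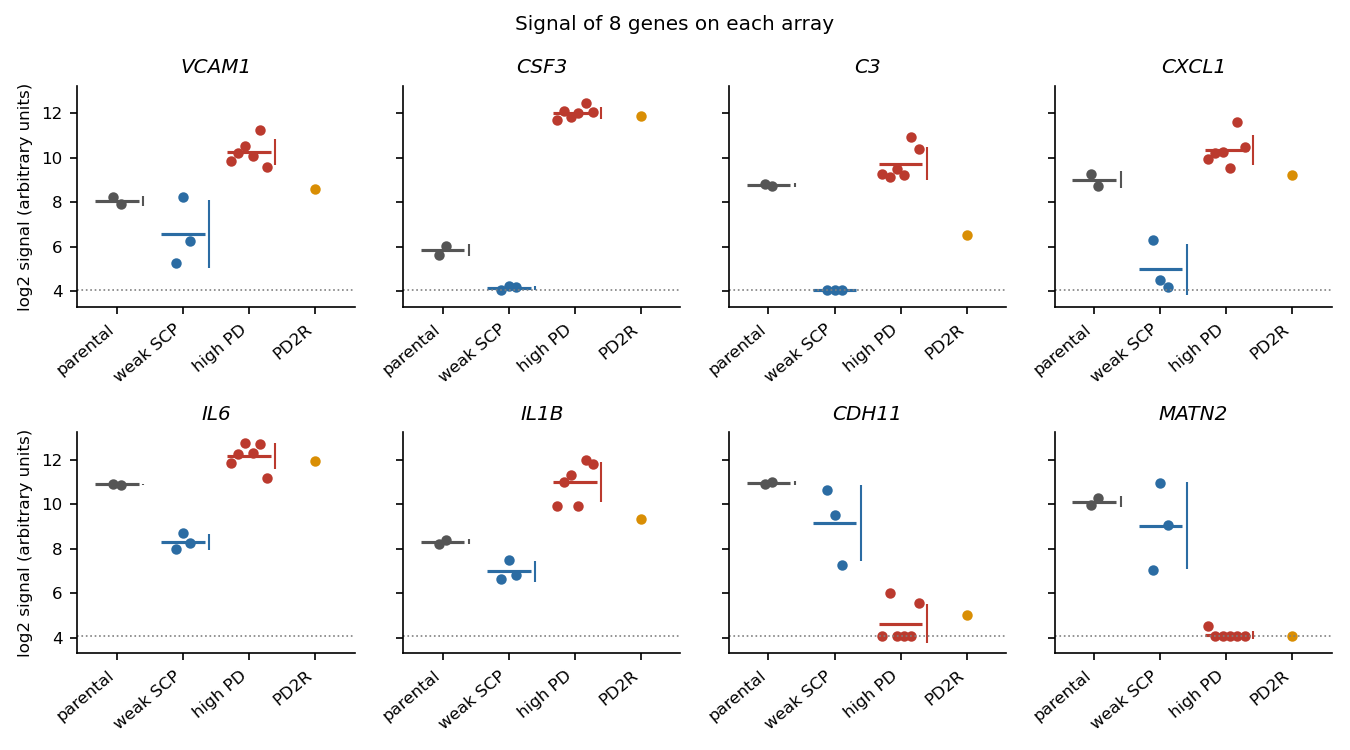
Log2 signal (arbitrary units) of 8 genes on each of the 12 arrays, by group; each point is 1 array, horizontal bars are group means, vertical lines extend 1 SD either way, and the dotted line is the floor at 4.06. CSF3 lay near the floor in weak SCP (mean 4.16) and at a mean of 12.03 in high PD, whereas MATN2 was at the floor on 5 of 6 high PD arrays.

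NF-kB targets and cytokines were both higher. These lists share members, CXCL1, CXCL2, CXCL8, IL6 and IL1B among them, so their results are not independent. Of 26 measured NF-kB target genes, 16 were higher in high PD, none was lower and 10 did not pass, with 17 higher when adjusted over the list alone. The median difference was 1.27, and examples are the syndecan SDC4 at 1.71 and the chemokine CXCL2 at 3.03. Limma's camera test placed this list above other genes (adjusted p = 1.28e-08), also with an estimated correlation (adjusted p = 0.0473). Of 27 cytokines and chemokines, 15 rose, none fell and 12 did not pass; adjusted over the list alone, 17 rose and 1 fell. LIF, a member of the IL6 family, rose by 2.13. The camera adjusted p was 7.58e-07, and the adjusted p = 0.0234 with an estimated correlation.

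Antigen presentation genes were also higher. Of 12 class II genes, 9 rose and 3 did not pass, with the same counts adjusted over the list alone and a median of 1.34. The protease CTSS rose by 2.78, the invariant chain CD74 by 1.49 and HLA-DMA by 1.18 (camera adjusted p = 1.53e-05, but adjusted p = 0.341 with an estimated correlation). Of 16 class I genes, 6 rose, including TAPBP at 1.61, PSMB8 at 0.96 and TAP1 at 0.92, and B2M fell at -0.70. Adjusted over the list alone, 7 rose and 2 fell. The list passed camera at an adjusted p = 0.0161, but had an adjusted p = 0.60 with an estimated correlation. B2M took the other sign, 0.16, after quantile normalization, and without SCP6 the list did not pass (adjusted p = 0.0891).

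Ribosomal protein and respiratory chain genes were lower. All 21 measured ribosomal protein genes fell, also adjusted over the list alone, by a median of -1.03, among them RPL6 at -1.10 and RPL18 at -1.06 (camera adjusted p = 4.84e-15, but adjusted p = 0.341 with an estimated correlation). The median was -0.20 after quantile normalization and -0.42 after cyclic loess normalization. Of 23 oxidative phosphorylation genes, 11 fell, 1 rose and 11 did not pass, with 16 lower and 1 higher adjusted over the list alone. NDUFS3 fell at -1.11 and COX6C at -0.63 (camera adjusted p = 0.00057, but adjusted p = 0.493 with an estimated correlation). Both lists hold bright genes, and genes above 11 on the log2 scale as a whole had a median difference of -0.23.

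The other 18 lists did not pass camera. Cell adhesion molecules went both ways, with 6 of 27 higher, including ICAM1 at 2.26 and ITGA5 at 1.36, and 5 lower, including ALCAM at -0.95; the same counts held adjusted over the list alone. Of 30 cell cycle genes, 12 fell, such as CCNB1 at -1.43 and TOP2A at -1.01, and 5 rose, such as E2F1 at 1.25; adjusted over the list alone, 14 fell and 6 rose, and the list median of -0.27 was near 0 after quantile normalization. Of 18 genes linked to lung metastasis, 6 rose and 1 fell, with TNC at 1.88 and FSCN1 at 2.34; without SCP3 this list, osteoclast regulators and cholesterol biosynthesis passed (each adjusted p = 0.0440). Of 18 linked to bone metastasis, 3 rose and 3 fell, with SRGN at 2.40 and LOX at -1.34. Osteoclast regulators had 5 of 19 higher and 1 lower, TGF-beta response genes 5 of 24 higher and 4 lower, and growth arrest and dormancy genes 4 of 25 higher and 2 lower. Mesenchymal genes had 5 of 25 higher and 5 lower, epithelial genes 5 of 27 higher and 3 lower, and extracellular proteases and inhibitors 6 of 28 higher and 4 lower. Interferon response genes had 1 of 27 higher and 4 lower, hypoxia genes 1 of 24 higher and 5 lower, glycolysis genes 1 of 18 higher and 7 lower (5 higher and 2 lower after quantile normalization), and unfolded protein response genes 4 of 21 higher and 3 lower. Cholesterol biosynthesis genes had none of 16 higher and 7 lower, and 8 lower adjusted over the list alone. Adjusted in that way, 1 further gene was lower among lung metastasis, TGF-beta response, mesenchymal and protease genes, and 1 further gene was higher among unfolded protein response genes. The median lay below 0 while the mean and the test lay above it for bone metastasis genes, osteoclast regulators and the unfolded protein response, and the mean alone lay below 0 for mesenchymal and protease genes. Markers of other cells barely differed: none of 18 leukocyte and bone marrow markers passed, 2 of 16 fibroblast and endothelial markers rose (ROBO4 at 0.88 and DCN at 0.78), and 1 of 13 osteoclast and osteoblast markers rose (RUNX2 at 1.97).

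**Figure D2:**
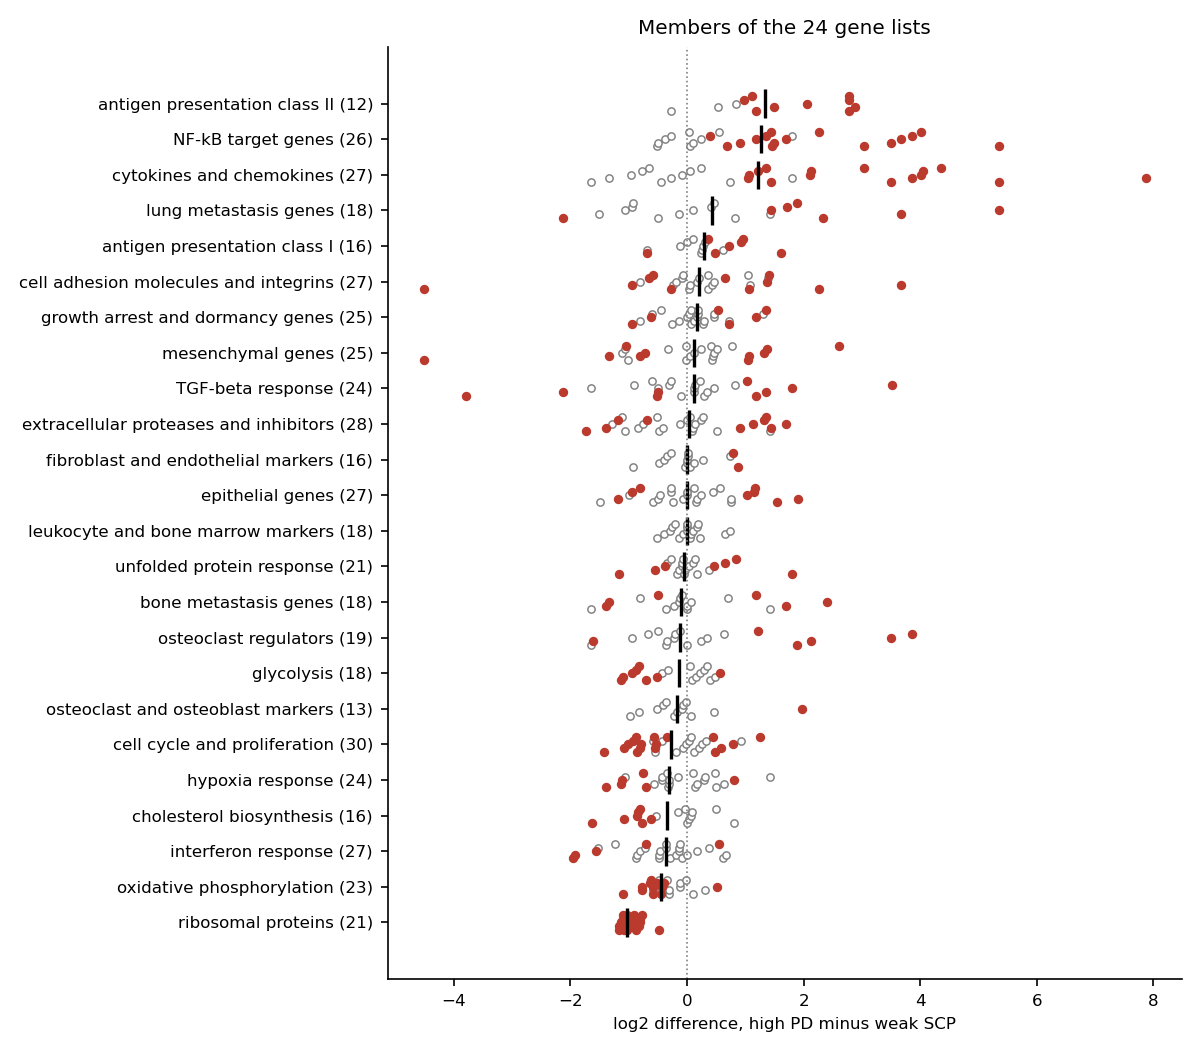
Log2 difference between high PD and weak SCP for each measured member of the 24 gene lists, with the number of measured members in brackets; filled points had a limma adjusted p under 0.05, open points did not, and black bars are list medians. The list medians run from -1.03 for ribosomal proteins to 1.34 for class II antigen presentation.

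Over all genes, 3217 of 11963 differed at an adjusted p under 0.05, 1446 higher and 1771 lower in high PD, and 1176 of them by at least 2-fold. In 3004 of all 11963 genes no array of either group lay within the range of the other, which chance gives for 2.38% of genes. Of 2252 further probe sets of the 3217 genes, 1670 had the same direction, and 67 passed in the opposite one. The 18 probe sets for hybridisation controls averaged 10.06 to 10.52 on the log2 scale on the 7 post-dormancy arrays and 11.41 to 11.93 on the 5 parental and SCP arrays, so that array set and group cannot be told apart here or in the comparisons of high PD with SCP6 and with the parental line. The difference between 3' and 5' probe sets of ACTB was 0.34 to 0.75 in weak SCP and -0.10 to 0.19 in high PD, that of GAPDH was -0.07 to 0.06 and -0.35 to -0.13, and the 99th percentile of signal was 14535 to 15303 units and 7567 to 10275 units, so that these measures of RNA and brightness also separated the groups.

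**Figure D3:**
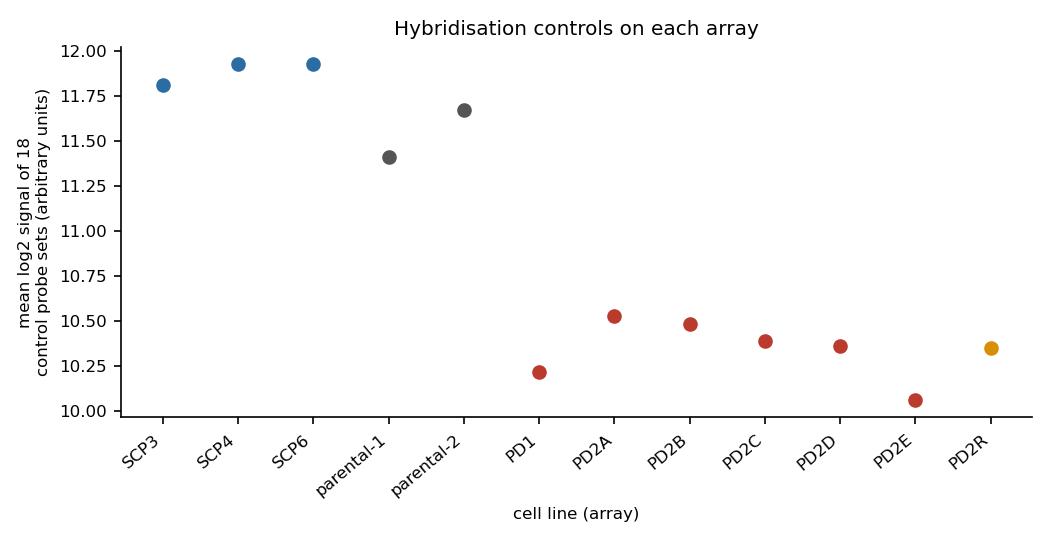
Mean log2 signal (arbitrary units) of the 18 hybridisation control probe sets on each array, 1 point per array, coloured by group (blue weak SCP, grey parental, red high PD, orange PD2R). The 5 parental and SCP arrays lie between 11.41 and 11.93, and the 7 post-dormancy arrays between 10.06 and 10.52.

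The second comparison set high PD against SCP6 alone, the variant from which these sublines descend, and so held the clone constant. CSF3 was higher in high PD by 7.85 ± 0.26 on the log2 scale (SE, n = 6 and 1, limma adjusted p = 3.16e-06), but SCP6 lay near the floor (4.18 against 4.06) and the difference was 5.86 with a floor at the 40th percentile. CXCL1 was higher by 6.16 and IL32 by 4.93. C3, at the floor in SCP6, was at least 51.0-fold higher, RRAD was higher by 4.47 and FKBP8 by 4.20. VCAM1 was higher by 4.0 ± 0.97 (adjusted p = 0.034); it also passed without PD2D or PD2E, but not without PD1, PD2A, PD2B or PD2C (adjusted p from 0.0519 to 0.0617). The largest decreases were MATN2 at -4.92, MYH10 at -4.05, LBH at -3.35, DLK2 at -3.34, the nuclear receptor cofactor NRIP1 at -3.30 and DOCK2 at -3.24. High PD was at the floor on 5 of 6 arrays for MATN2 and LBH, 4 for DOCK2 and 3 for NRIP1, so these give no order.

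Of 24 lists, 9 passed camera in this comparison, 7 upward and 2 downward. The NF-kB, cytokine, lung metastasis and osteoclast regulator lists share members, CXCL1, IL6 and CXCL8 among them, so their results are not independent. Among NF-kB targets 12 of 26 rose and none fell, the same adjusted over the list alone (adjusted p = 0.0909 with an estimated correlation). Among cytokines 13 of 27 rose and none fell, with 14 higher adjusted over the list alone, and this list alone held with an estimated correlation (adjusted p = 0.0263). Genes linked to lung metastasis had 5 of 18 higher, with FSCN1 at 3.29 and TNC at 2.18 (adjusted p = 0.122 with an estimated correlation). Osteoclast regulators had 5 of 19 higher, with GDF15 at 2.95, though their median of 0.06 was -0.20 on the deposited ratios without a floor (adjusted p = 0.157 with an estimated correlation). Of 25 growth arrest and dormancy genes, 2 rose, the cell cycle inhibitor CDKN1A at 2.5 and GADD45B at 0.62 (adjusted p = 0.133 with an estimated correlation). Class I genes had 3 of 16 higher and 1 lower, and class II genes 3 of 12 higher (each adjusted p = 0.389 with an estimated correlation). Oxidative phosphorylation genes had 8 of 23 lower, with NDUFS3 at -1.40, and ribosomal protein genes 18 of 21 lower (adjusted p = 0.389 and 0.327 with an estimated correlation). Of the oxidative phosphorylation genes 4 were lower after quantile and after cyclic loess normalization. For ribosomal proteins 6 were lower and 1 higher after quantile normalization, and 6 were lower after cyclic loess normalization, with the median moving from -0.96 to -0.26 and -0.42. Of 18 leukocyte and bone marrow markers, 2 were higher, CD2 at 1.90 and ITGAM at 1.38, and none adjusted over the list alone. Adjusted over the list alone, 21 ribosomal protein genes were lower, and 4 growth arrest, 5 class I and 4 class II genes were higher.

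Altogether 1528 genes differed between high PD and SCP6, 618 higher and 910 lower. SCP6 was a single array, assumed to vary like the other groups. On the deposited ratios without a floor, with probe sets averaged per gene, 822 genes passed.

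The third comparison set high PD against the parental population from which all lines derive. CSF3 was higher in high PD by 6.19 ± 0.18 on the log2 scale (SE, n = 6 and 2, limma adjusted p = 6.70e-07) and IL1A by 4.66. LAT2, at the floor on both parental arrays, was at least 19.6-fold higher by the probe set used. Between high PD and weak SCP that probe set differed by 2.38, and a second, with a mean log2 signal of 6.76, by -0.34. The cyclin CCND2 was higher by 3.43, the germline antigen gene MAGEB2 by 3.34, and C1orf115, at the floor in the parental line, by at least 8.68-fold. CDH11 was lower at -6.33, MATN2 at -5.99, the secreted trefoil peptide TFF1 at -4.97 and the transcription factor SOX4 at -4.84, with high PD at the floor on 4, 5, 5 and 2 of 6 arrays, so that these sizes are understated. AGR2 and WNT5B were at the floor on all high PD arrays and at least 35.9-fold and 19.1-fold lower. VCAM1 was 2.19 ± 0.70 above the parental line and did not pass (adjusted p = 0.066), although each of the 6 high PD arrays lay above both parental arrays.

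The NF-kB and cytokine lists did not pass camera here: 3 of 26 NF-kB targets were higher and 2 lower, and 6 of 27 cytokines were higher and 2 lower. CCL2, a monocyte-attracting chemokine, was lower at -2.5, while LIF was higher by 2.05. The 5 lists that passed all moved down, and none held with an estimated correlation. They were ribosomal proteins (18 of 21 lower, median -0.72, but 6 lower and 1 higher with a median of -0.13 after quantile normalization and 12 lower with -0.39 after cyclic loess normalization), hypoxia response (4 of 24 lower, LDHA at -0.96 and PDK1 at -1.44) and cholesterol biosynthesis (2 of 16 lower, DHCR7 at -1.42), each with an adjusted p = 0.542 with an estimated correlation. Glycolysis (6 of 18 lower and 1 higher, GAPDH at -1.10) and the cell cycle (5 of 30 lower and 1 higher, CCNB1 at -0.87) had an adjusted p = 0.854 with an estimated correlation. Adjusted over the list alone, 21 ribosomal protein, 7 glycolysis and 6 cell cycle genes were lower, 6 NF-kB targets were higher and 3 lower, and 7 cytokines were higher and 2 lower.

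In all, 1880 genes differed between high PD and the parental line, 1114 higher and 766 lower. Leaving out the first parental array left 963, and leaving out the second left 631. SOX4, AGR2, C1orf115 and GAPDH did not pass when either was left out, and CCNB1 and PDK1 did not pass without the second; CCL2 and LIF were not run in this way.

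The fourth comparison set weak SCP against the parental line. C3 was at the floor in all 3 variants and at least 26.1-fold lower (limma adjusted p = 0.00433). The neutrophil chemokine CXCL8 was lower by a log2 difference of -4.36 ± 0.47 (SE, n = 3 and 2, adjusted p = 0.00402), CXCL1 at -4.03, IL32 at -3.55 (1 of 3 variants at the floor), VWA1 at -3.44 (2 of 3 at the floor) and the trefoil peptide TFF2 at -3.23. Without the first or second parental array CXCL1 (adjusted p = 0.0955 and 0.0704), IL32 (adjusted p = 0.147 and 0.153) and TFF2 (adjusted p = 0.071 and 0.107) did not pass. Higher in the variants were the ribosomal protein genes RPLP2 at 2.69 and RPL27A at 2.48, the pseudogene OR7E47P at 2.67, SNAP25 at 2.56, the xenobiotic-metabolising enzyme CYP1A1 at 2.40 and the complement factor CFD at 2.36. The parental arrays differed widely for some of these, and SNAP25, CYP1A1 and CFD were at the floor on 1 of the 2. Between high PD and weak SCP the SNAP25 probe set used differed by -0.57, and a second, dimmer one by 1.94. RPLP2 rests on 1 probe set with a mean log2 signal of 7.17 over all arrays. This is dim for a ribosomal protein gene, and its other probe set lay near the floor at 4.22. Without the first or second parental array RPLP2 differed by 3.81 or 1.57, SNAP25 by 3.53 or 1.59, CYP1A1 by 3.47 or 1.33 and RPL27A by 2.0 or 2.97. Without the second, RPLP2, SNAP25 and CYP1A1 did not pass (adjusted p = 0.108, 0.124 and 0.156), and OR7E47P did not pass when either was left out (adjusted p = 0.143 and 0.162). VCAM1 differed by -1.47 ± 0.78 and did not pass (adjusted p = 0.329).

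Of 26 NF-kB targets, 10 fell and none rose, with 12 lower adjusted over the list alone, a median of -1.04 and RELB at -1.54 (adjusted p = 0.0128 with an estimated correlation). Of 27 cytokines 9 fell, including CXCL8, and of 19 osteoclast regulators 5 fell, including CSF1 at -1.76, the same counts adjusted over the list alone; both lists also had an adjusted p = 0.0128 with an estimated correlation. The NF-kB, cytokine and osteoclast regulator lists share members, IL6, CXCL8 and CCL2 among them, so these results are not independent. The other 6 lists that passed camera were lost with an estimated correlation. Class II genes had 3 of 12 lower, 7 adjusted over the list alone, with HLA-DMA at -1.75 and CD74 at -1.53 (adjusted p = 0.166 with an estimated correlation). Class I genes had 2 of 16 lower, 4 adjusted over the list alone, with TAPBP at -1.32 (adjusted p = 0.237 with an estimated correlation). Genes linked to lung metastasis had 1 of 18 lower, CXCL1 (adjusted p = 0.166 with an estimated correlation), and TGF-beta response genes 2 of 24 lower, TGFB2 at -1.68 and TGFBR1 at -2.01, and 1 higher (adjusted p = 0.335 with an estimated correlation). Oxidative phosphorylation genes had 2 of 23 higher, 4 adjusted over the list alone, with NDUFB8 at 0.96 (adjusted p = 0.35 with an estimated correlation). Ribosomal protein genes had 3 of 21 higher, with RPL11 at 0.69 (adjusted p = 0.46 with an estimated correlation), and their median of 0.26 turned to -0.01 after cyclic loess normalization. Without the first or second parental array TAPBP (adjusted p = 0.223 and 0.11), PDIA3, the other class I gene that passed (adjusted p = 0.0897 and 0.168), TGFBR1 (adjusted p = 0.0511 and 0.0939), CCN2, the TGF-beta response gene that was higher (adjusted p = 0.083 and 0.105), and RPL11 (adjusted p = 0.0955 and 0.137) did not pass. RELB did not pass without the first (adjusted p = 0.0702).

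Between weak SCP and the parental line 441 genes differed, 288 higher and 153 lower, against 246 higher and 238 lower after quantile normalization and 168 higher and 209 lower after cyclic loess normalization. The median of all genes was 0.10 before normalization, 0.04 after the first and 0.02 after the second. The hybridisation controls lay higher on the 3 SCP arrays (11.81 to 11.93) than on the parental arrays (11.41 and 11.67), as did the 3' to 5' difference of ACTB (0.34 to 0.75 against -0.15 and -0.13), that of GAPDH (-0.07 to 0.06 against -0.20 and -0.19) and the 99th percentile of signal (14535 to 15303 units against 12208 and 12640.3), so that these measures and the group cannot be told apart here either. Fitted on these 5 arrays alone the count was 1, and leaving out the first or second parental array left 264 or 197.

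The fifth comparison set the mildly metastatic PD2R against its siblings PD2A to PD2E. PD2R was a single array, assumed to vary like the other groups. Few genes differed: 11 were higher and 1 lower in PD2R by limma at an adjusted p under 0.05, out of 642 with an unadjusted p under that value. The number of 642 is close to what chance gives over the 11963 genes. The synaptic vesicle genes SV2B and SV2A were higher by 2.12 and 1.78, ATP2A3 by 1.51 and OR12D3 by 1.41. ATP2A3 rests on 1 probe set, and its other probe sets had mean log2 signals of 4.06, the floor, or 4.09. SERPING1 and KCNJ10, at the floor in all 5 siblings, were at least 2.37-fold and 2.07-fold higher. TTC1 was lower at -0.96. VCAM1 was lower in PD2R by a log2 difference of -1.72 ± 0.98 (SE, n = 1 and 5) and did not pass (adjusted p = 1). Its log2 signal of 8.61 in PD2R lay below all 6 high PD arrays and above all 3 SCP arrays. Ribosomal proteins were the only list past camera, with a median of 0.25 and no member passing, falling to 0.02 after quantile normalization (adjusted p = 0.743 with an estimated correlation). In all 11 higher genes at least 3 of the 5 siblings lay at the floor, while the log2 signal in PD2R was 4.55 to 6.31. Their calls were lost on the deposited ratios without a floor. The count of 12 was 23 without PD2E, 7 without PD2B and 4 without PD2C or PD2D.

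Over the 3217 genes that differed between high PD and weak SCP, PD2R was placed at 0.94 of the way from the weak SCP mean to the high PD mean. The 6 high PD lines, each placed on genes chosen without it, lay between 0.89 and 1.01, so that PD2R was within their range. PD2R shares the array set of the high PD lines, which by itself would place it near them. This position therefore cannot separate the line from its array set. The parental arrays, which share the array set of the SCP lines, lay at 0.41 and 0.32. The SCP lines, placed in the same way, lay at 0.10, 0.15 and 0.19. On the called NF-kB targets and cytokines PD2R lay at 0.89, and the parental arrays at 0.63 and 0.54.

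**Figure D4:**
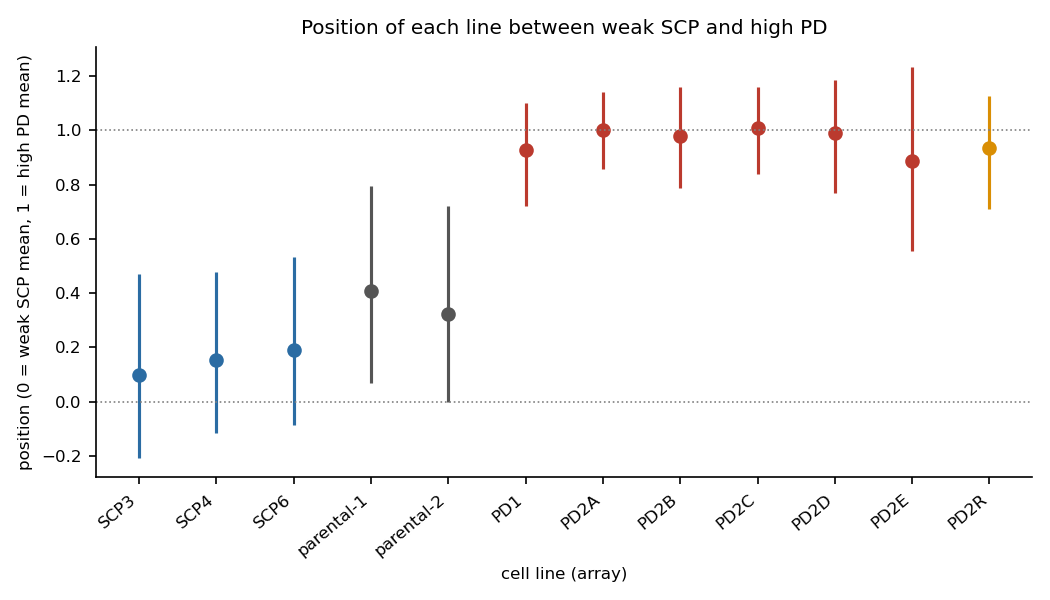
Median position of each line between the weak SCP mean (0) and the high PD mean (1) over the genes that differed between these groups; vertical lines span the 25th to 75th percentile over genes. PD2R (0.94) lies within the range of the 6 high PD lines (0.89 to 1.01), and the parental arrays lie at 0.41 and 0.32.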

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

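The tests of the array set and of the SCP6 founder, and the lists matched without other ribosomal protein genes, were chosen after the result was seen; the tests of other splits, of brightness and of the floor were set before theirs.

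The 18 hybridisation control probe sets, which no comparison used, were lower on the 7 post-dormancy arrays than on the 5 parental and SCP arrays by a mean log2 difference of -1.41, and all 18 went the same way, which bears on the 3217 genes that differed between high PD and weak SCP. Chance labelling of exchangeable arrays can be excluded for that count: 1 of the 84 splits of the 9 arrays, the real one, gave as many genes, and the highest of the others gave 39. That count treats the 9 lines as independent, whereas the 6 high PD lines are a single lineage, so that a change fixed once in PD1 would give the same result. SCP6 lay at 0.19 of the way from the other SCP lines to high PD on genes chosen without it (75th percentile over genes 0.53). SCP6 shares the array set of the other SCP lines, which by itself would place it near them. This value therefore cannot decide whether genes already set in the founder contributed. The array set also stays open, because the -1.41 step in the controls follows the groups exactly and cannot be told apart from them. The 3' to 5' differences and the brightness of the arrays cannot be told apart from the groups either. Untested differences between the lines themselves, drift in the PD1 lineage included, stay open as well.

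The lower ribosomal protein signal in high PD was set against brightness. Of 10000 lists matched on mean signal, 3 had a median as low as -1.03, but their own median was -0.75, and cyclic loess normalization brought the list to -0.42. Drawn without other ribosomal protein genes, the matched lists had a median of -0.72 as scaled, -0.09 after that normalization and 0.07 after quantile normalization (list -0.20), and 0, 1 and 2 of 10000 were as low as the list. Brightness-dependent scaling may therefore account for much of the size, and these values leave open whether it accounts for all of it. Each matched list was drawn gene by gene, so the draws ignore correlation among ribosomal protein genes and may spread too little. The array set stays open here too.

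For the 11 genes higher in PD2R, the floor on dim signals is a candidate explanation. In all 11, at least 3 of the 5 siblings lay at the floor, which leaves little spread, and 0 of the 11 passed on the ratios without a floor (smallest adjusted p 0.194), although all 11 kept their direction. No biological explanation was tested.

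Within high PD, 52 quantities were checked for a line far from the others, and 11 were found. Chance finds about 1 in 20, but that rate does not hold where the other lines all lay at the floor, as for MATN2, CPE, LBH and COCH, since any value above the floor is then found. PD2E was the dimmest high PD array at the 99th percentile of signal (7567 units, against 9593 to 10275 units). For lists of bright genes, the line and the brightness of its array cannot be told apart. In PD2E the mean log2 signal was lowest for cell cycle genes (10.19), class I genes (11.34), glycolysis (11.52), oxidative phosphorylation (11.36) and ribosomal proteins (13.08). The others were single lines above lines at or near the floor: PD1 for MATN2 (4.51), DOCK2 (5.05) and COCH (4.25), PD2E for CPE (4.70), PD2B for LBH (5.60) and PD2C for IRX5 (5.34).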

How the results depend on the processing

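The ratios without a floor, cyclic loess normalization and the brightness-relative differences were chosen after seeing the data. VCAM1 between high PD and weak SCP kept its direction and its side of the threshold under every alternative run, from 3.0 to 4.50 on the log2 scale when single arrays were left out (adjusted p over all alternatives from 8.88e-05 to 0.0118). The number of genes differing between high PD and weak SCP ranged from 2657 to 3265 when single arrays were left out; for SCP6 the range was 1113 to 1823, for high PD against parental 631 (without the second parental array; 963 without the first) to 2097, for weak SCP against parental 197 (without the second parental array; 264 without the first) to 659, for PD2R 4 (without PD2C or PD2D; 7 without PD2B) to 23 (without PD2E), and for the lists between high PD and weak SCP 5 to 9. In the order high PD against weak SCP, SCP6 and parental, weak SCP against parental, and PD2R, every probe set tested on its own gave 5461, 2668, 2978, 833 and 56, in probe sets and not genes, and a 2-fold minimum gave 1176, 852, 791, 187 and 6, through its own construction. For weak SCP against parental the count was 290 without the 30% dimmest genes, 290 with a floor at the 10th percentile, 1 on the compared arrays only and 147 on ratios without a floor; for SCP6 that last setting gave 822. PD2R gave 29 with quantile normalization, 0 without the 30% dimmest genes (limma, 392 at an unadjusted p under 0.05), 5 without the dimmest 50%, 0 with an intensity trend (limma, 581 at that level), 130 on the compared arrays only, 5 and 77 with floors at the 10th and 40th percentile, 0 on ratios without a floor (limma, 513 at that level with probe sets averaged) and 2 with cyclic loess. With an estimated correlation 2 lists remained between high PD and weak SCP and 1 between high PD and SCP6. After quantile and after cyclic loess normalization 6 lists passed between high PD and weak SCP, of which 5 were among the 6 reported. Without the 30% dimmest genes 5 of those 6 passed. B2M turned to 0.16 (against weak SCP) and 0.14 (against SCP6) with quantile normalization, and TNFRSF11B in weak SCP against parental to 0.091 with a floor at the 10th percentile. For PD2R, the 392, 581 and 513 genes under the unadjusted threshold were no more than chance gives over the genes tested. Where no construction is named, the cause was not tested. Of 3491 values of named genes under alternatives, 3151 kept direction and side of the threshold, 297 lost and 40 gained the call and 3 reversed; 7 had no value at the higher floor. The floor sets what dim genes can show. No paired analysis was possible because only the parental arrays carry replicate numbers in the labels.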

Other observations

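The family test below was chosen after the data were seen, and so was the count of lines that lie beyond the others.

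Genes were grouped by the letters that open their symbols, which gave 223 families of at least 8 measured genes, and each was tested for an excess of called genes (Fisher's exact test, one-sided, 1784 tests in 4 comparisons, Benjamini-Hochberg); 17 passed. This test takes the genes of a family as independent, and its p-values are too small where they move together. Camera with an estimated correlation, which kept few of the lists above, was not run on the families. Mitochondrial ribosomal protein genes (MRPL) were lower in high PD than in weak SCP in 16 of 31, where 4.59 were expected (adjusted p = 0.000364), and higher in 3. MRPL15 differed by -1.44 and MRPL48 by -1.22. Unlike the cytosolic ribosomal proteins, this family kept its median under each scaling, at -0.59 as reported, -0.59 after quantile and -0.55 after cyclic loess normalization. Against SCP6 11 of 31 were lower, and against the parental line 10 of 31. Translation initiation factors (EIF) were lower in 21 of 43 against weak SCP, where 6.37 were expected (adjusted p = 3.37e-05), with a median of -0.35 that moved to -0.20 after cyclic loess normalization.

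A further pair of families separated high PD from the parental line. Pregnancy-specific glycoprotein genes (PSG) were lower in 5 of 9 (0.576 expected, adjusted p = 0.0148), with PSG5 at -3.21 and PSG11 at -2.53; their median was -1.51 and, after cyclic loess normalization, -1.58. These genes are close copies, and signal shared between their probe sets was not excluded. Transfer RNA methyltransferase genes (TRMT) were higher in 6 of 12 (1.12 expected, adjusted p = 0.0405), with TRMT13 at 1.55 and TRMT44 at 1.45. After quantile and cyclic loess normalization 5 of 12 were higher, and the unadjusted p rose from 0.000363 to 0.00255 and 0.00163 (Fisher's exact test), with no adjustment repeated for these scalings. HLA genes were higher in 10 of 21 against weak SCP (adjusted p = 0.00958), and 4 of 21 were lower in weak SCP than in the parental line (adjusted p = 0.0166).

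PD2R lay beyond all 6 high PD lines on the side of weak SCP in 22.0% of the 3217 called genes. PD2E lay beyond the other 6 post-dormancy lines in 22.7%, against 14.3% by chance if all lines were alike. The high PD lines, unlike PD2R, had a part in choosing these genes. That choice alone moves PD2R toward weak SCP, so 14.3% is not its chance rate. Among the 24 genes with the largest differences, PD2R lay beyond all 6 high PD lines in 10. These include VCAM1, at 0.55 of the way to high PD, and C3, at 0.44. The 24 genes were chosen, without PD2R, for high PD lying far from weak SCP. This favours the same direction, and no expected count was formed. No test bears on whether PD2R differs from PD2E in this.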
